A study of Mus musculus with 88 samples.

How the data were processed

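Bone marrow cells of female C57BL/6J mice were grown with GM-CSF into dendritic cells, pooled before stimulation, and given LPS or a mock stimulus, per the labels. In pulsed SILAC the M form (Arg6, Lys4) marks protein made before the switch of medium at 0 h, the H form (Arg10, Lys8) protein made after it, and the L form an unlabelled mix added to each run as a common reference, per the labels' protocols. The labels gave treatment, time, channel and replicate number for all 88 samples. The protocol text describes harvests up to 12 h, and whether the 24 h samples of the labels were handled alike is not given in the sources used here, so results at 24 h carry that doubt. They do not say that replicates 1 and 2 came from separate cultures, so p-values measure the spread between these samples, which may be technical. The make-up of the light mix, the search software's version and its settings are not given in the sources used here. Column names are those MaxQuant writes, per the file headers, and the submitters' processing notes list the genome build mm9.

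The authors deposited, per protein group and run, the SILAC ratio of M/L, H/L and H/M, both as measured and in a normalised column, per the file headers. The ratio count deposited beside each ratio is the number of peptide pairs behind it, and it was used as a filter and as the measure of depth. The deposited intensity values are peptide intensities summed per channel, and iBAQ is that intensity divided by the number of peptides a protein could give, per the file headers. The un-normalised ratios were the planned choice. Once opened, the deposited normalised log2 ratios had group medians from -2.14 to 1.80 for H/L and from -2.01 to 1.82 for H/M over time, and so were not on 1 scale. M/L and H/L of a run share the light signal as denominator. A run held 68083 to 109064 M/L peptide pairs (median 89439). The number of pairs limits the precision of a ratio, and no counting interval was computed since pairs are not independent molecules.

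Of 6266 trypsin protein groups, 90 marked as reverse, 97 as contaminants and 216 as identified by site alone were left out (a group can carry more than 1 mark), and 5899 were kept. Of these 115 had no gene name and are not named, and 239 had several, of which the first was used. A name was a current symbol of the gene table for 5321 groups and was matched through an older synonym for 421, and 72 names were carried by more than 1 group. Of the AspN groups 3752 of 3839 and of the LysN groups 4049 of 4138 were kept. No per-sample column was left unmatched to a sample (0).

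Each run's ratios were divided by a run factor, the median of M/L plus H/L over the 2628 proteins with M/L in every run (log2 -0.68 to 0.69). New protein is log2 H/L, pre-existing protein log2 M/L and total protein log2 of their sum, with H/M tested without the factor. Each was fitted with limma 3.58.1 in R 4.3.3 as means of the 21 groups, and contrasts gave LPS minus mock over 6, 9 and 12 h (late, 6 against 6 samples), over 1, 2 and 3 h (early), at 24 h, late minus early, and at each time. A protein was tested with at least 4 of 6 values in each late arm. Adjusted p is Benjamini-Hochberg over all proteins of a comparison, called under 0.05. Replacement was the slope of log2 of the M share, -log2(1 + H/M), on time from 0.5 to 12 h in at least 12 of 18 mock samples, with half-time -1/slope, which takes no account of growth. LPS and mock slopes were compared in 1 fit. Proteins with H/L in at least 5 of 6 late samples of 1 arm and at most 1 of 6 of the other were listed without a test of each. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

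These tests and 24 gene lists were fixed in advance, before the files were opened. The lists were interferon-stimulated proteins, NF-kB targets and inflammatory mediators, dendritic cell maturation, MHC class I and II pathways, cytosolic and mitochondrial ribosome, oxidative phosphorylation, constitutive proteasome, glycolysis, pentose phosphate and NRF2 targets, lysosome, phagocytic and pattern recognition receptors, sterol biosynthesis, translation factors, replication and cell cycle, histones, ER and cytosolic chaperones, actin and adhesion, and granulocyte, macrophage, erythroid and platelet, and lymphocyte markers of other cells. Lists with at least 3 tested members were compared with all other proteins by camera on limma's moderated t with a preset correlation of 0.01, and again with a correlation estimated from residuals. Camera compares a list with other proteins, so it can call a list whose own median is near 0. The erythroid and platelet list (Pf4 and Ca2) had too few members for camera. Hspd1 and Hspe1 of the cytosolic chaperone list are mitochondrial. Where camera's call of an estimated correlation is not mentioned, the call held.

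Proteins were named by rule. For new protein late these were the 12 highest and 12 lowest changes among those called with LPS on the same side of mock in every pair of the same time and replicate (at least 4 pairs). For pre-existing and total protein they were 8 and 8, for H/M, early, 24 h and late minus early 4 and 4, and for replacement the 6 fastest and 6 slowest with at least 2 unique peptides. Up to 4 members with the highest absolute t were named per list. Apart from replacement and list members, the same side in every pair was a condition for naming, so it is no added support for those proteins. Some proteins that met these rules are not reported here.

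Replicate numbers come from the labels and paired the samples. The deviations of same-numbered LPS and mock samples from their group means correlated over 0.1 at each of 10 times (0.234 to 0.470 for H/L, 0.315 to 0.572 for M/L, 0.320 to 0.509 for the sum and 0.237 to 0.477 for H/M). A fit with the replicate number as a block was also run.

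The fits were tested on simulated data with the real proteins' means, spread and missing values and 200 changed proteins, 50 per size. The simulated noise was drawn independently for each protein and sample. It lacks the deviations that samples of 1 replicate number share in the real data, so rates in the real data may differ. Late, the share of simulated 2-fold changes called was 50% in H/L, 96% in M/L, 88% in total protein and 56% in H/M, and of 1.25-fold changes 4%, 76%, 50% and 2%. Early it was 36%, 92% and 94% for 2-fold changes in H/L, M/L and total protein, at 24 h 20%, 82% and 82%, and for late minus early in H/L 24%. False calls were 10.5% of calls for H/M and 1.19% for H/L late. Among mock slopes, half-times of 12 h were called in 86% and of 96 h in 18% of cases, and a steeper LPS slope in 88% and 28%. The list test, on simulated t values without correlation between proteins, called the 1 shifted list alone.

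Alternatives were no run factor, each channel centred on its own median, the deposited normalised ratios, summed intensities, ratio count of at least 3, at least 2 unique peptides, stricter and looser filters on missing values, other windows and samples in the fit, time as a factor, a robust trended prior, the replicate block, lines without an intercept, and leaving out replicates or single late samples. Subtracting H/L at 0 h, leaving out the 0.5 h samples, the block at each time, 0 h replicates alone, and no run factor with the block or without the LPS 12 h run of replicate 2 were chosen after seeing the data. The AspN and LysN digests come from separate tables and were compared with trypsin by shares and ranks alone.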

Results

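The data followed the proteome of dendritic cells grown from the bone marrow of female C57BL/6J mice with GM-CSF, after lipopolysaccharide (LPS, a bacterial wall component, 100 ng per ml) or a mock stimulus. Cells grown in medium-labelled amino acids (M) were switched to heavy-labelled amino acids (H) at 0 h, so that M marks protein made before the stimulus and H protein made after it, and both were measured against a common mix of unlabelled cells (L). The series held 88 samples. Of these, 84 were the M and H channels of 42 trypsin runs in 21 groups of 2 replicates, namely 0 h and 10 later times from 0.5 to 24 h under each treatment. The others were 2 unlabelled 0 h samples digested with AspN and 2 digested with LysN. A run gave an M/L ratio for 3575 to 4338 proteins, from 68083 to 109064 M/L peptide pairs with a median of 8 to 10 pairs per protein, and an H/L ratio for 3538 to 4082 proteins. The comparisons asked how the making, the loss and the level of each protein responded to LPS. Changes are log2 of LPS over mock with the standard error, and "late" is the mean over 6, 9 and 12 h (6 samples in each arm). Rose and fell compare LPS with mock at the same times, not with 0 h. Scaled ratios at single times are means ± SD with n = 2.

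Late after LPS, newly made protein rose most for cytokines and interferon-induced proteins. New interleukin-1β (Il1b), the precursor of a fever-inducing cytokine, rose by 4.75 ± 0.26 (adjusted p = 1.44e-12), a fold of 27.0, and its scaled H/L at 12 h was 2.44 ± 0.222 after LPS against 0.104 ± 0.0303 in mock cells. New Il1a, its sister cytokine, rose by 4.26 ± 0.30 (adjusted p = 1.17e-10), and the chemokine Ccl5 by 3.92 ± 0.40 (adjusted p = 5.95e-08). Irg1, the enzyme that makes itaconate in activated macrophages, rose by 3.71 ± 0.16 (adjusted p = 3.16e-14), a fold of 13.1, from 0.056 ± 0.0094 to 1.02 ± 0.127 at 12 h. The mock values of Il1b and Irg1 lay below the median scaled H/L of 0.135 at 0 h, before heavy label. The size of both folds therefore depends on background signal. The co-stimulatory receptor Cd40 rose by 3.46 ± 0.50 (adjusted p = 1.22e-05) and Bst2, which tethers budding viruses, by 3.22 ± 0.60 (adjusted p = 0.000314). Among the 12 highest were also the immunity-related GTPases Irgm1 (3.05 ± 0.26, adjusted p = 3.88e-09) and Ifi47 (2.99 ± 0.16, adjusted p = 4.58e-13). They also held the interferon-induced Xaf1 (3.03 ± 0.27, adjusted p = 6.78e-09) and the actin-associated Marcksl1 (2.88 ± 0.18, adjusted p = 2.55e-11). Each of these was higher in 6 of 6 pairs of the same time and replicate. Mndal, an interferon-induced DNA-binding protein, rose by 3.16 ± 0.31 (adjusted p = 2.16e-07, higher in 4 of 4 pairs). Its relative Ifi204, listed here with no unique peptide and a name shared with another protein group, rose by 2.94 ± 0.35 (adjusted p = 3.87e-06, 5 of 5 pairs).

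Lowest in the new fraction was Csf1r, the receptor for macrophage colony-stimulating factor, which changed by -1.81 ± 0.13 (adjusted p = 1.75e-10). Its scaled H/L at 12 h was 0.687 ± 0.137 after LPS and 1.26 ± 0.117 in mock cells. New apolipoprotein E (Apoe), a lipid carrier secreted by macrophages, changed by -1.25 ± 0.12 (adjusted p = 3.47e-08), from 1.48 ± 0.0147 in mock to 0.572 ± 0.0998 after LPS at 12 h. The elastase Mmp12 (-1.30 ± 0.14, adjusted p = 2.01e-07) and the endosomal Rab11fip5 (-1.36 ± 0.28, adjusted p = 0.00113) fell. The inflammation inhibitor Tnfaip8l2 (-1.23 ± 0.21, adjusted p = 9.56e-05) and glutamine synthetase Glul (-0.98 ± 0.16, adjusted p = 7.50e-05) fell too. So did the granule proteins Ngp (-1.37 ± 0.24, adjusted p = 0.000189) and lactoferrin Ltf (-1.19 ± 0.18, adjusted p = 2.11e-05). Each was lower in 6 of 6 pairs, and the receptor Tnfrsf26 in 5 of 5 (-0.96 ± 0.19, adjusted p = 0.00209). Plcb3 (-1.59 ± 0.47, adjusted p = 0.0247), Ttc7a (-1.54 ± 0.43, adjusted p = 0.0152) and the adhesion receptor Cd97 (-1.10 ± 0.34, adjusted p = 0.0301) were also lower in 6 of 6 pairs. Each of these 3 lost its call in at least 1 alternative setting. From summed intensities, Ngp (-0.80) and Ltf (-0.41) no longer passed. H/L counts the new protein still present, so slower making and faster loss both lower it, and they were not separated here.

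Most groups of immune proteins fixed before the data were examined rose together in the new fraction. Of 47 measured interferon-stimulated proteins 38 rose and 9 did not pass (42 rose when adjusted over the list alone), with a median change of 1.87 and a camera adjusted p = 5.51e-54. Rsad2, also called viperin, rose by 2.40 ± 0.12 (adjusted p = 2.95e-13), Ifi205a by 2.74 ± 0.15 (adjusted p = 9.26e-13) and the guanylate-binding Gbp5 by 2.56 ± 0.16 (adjusted p = 2.55e-11). Of 22 NF-kB targets and inflammatory mediators 20 rose (20 adjusted over the list alone; median 1.85, camera adjusted p = 3.75e-50), among them the autophagy receptor Sqstm1 (2.08 ± 0.09, adjusted p = 3.16e-14). Of 7 dendritic cell maturation proteins 5 rose (7 adjusted over the list alone; camera adjusted p = 3.65e-06). The checkpoint ligand Cd274 changed by 2.51 ± 0.22 (adjusted p = 2.74e-07), the hyaluronan receptor Cd44 by 1.24 ± 0.22 (adjusted p = 0.000162) and the actin bundler Fscn1 by 1.44 ± 0.26 (adjusted p = 0.000185). In the MHC class I pathway, which presents peptides to CD8 T cells, 7 of 12 rose (7 adjusted over the list alone; median 0.84, camera adjusted p = 6.74e-09). They included the proteasome activator Psme2 (1.54 ± 0.11, adjusted p = 8.26e-11), the immunoproteasome subunit Psmb10 (1.57 ± 0.15, adjusted p = 2.18e-08), the light chain B2m (1.04 ± 0.10, adjusted p = 1.23e-08) and H2-K1 (1.34 ± 0.19, adjusted p = 1.05e-05). Every example named here was higher in 6 of 6 pairs. In the MHC class II pathway the protease Lgmn fell (-0.83 ± 0.22, adjusted p = 0.00882, lower in 6 of 6 pairs). The other 6 of 7 did not pass (1 fell adjusted over the list alone; camera adjusted p = 0.355), with H2-Ab1 at 0.43.

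New protein of the translation machinery was also higher. Of 72 cytosolic ribosomal proteins 27 rose (36 adjusted over the list alone; median 0.53, camera adjusted p = 5.75e-07). Rps29 was at 1.24 ± 0.11 (adjusted p = 6.93e-09) and Rpl29 at 1.18 ± 0.20 (adjusted p = 9.77e-05). Of 48 translation factors 12 rose (13 rose and 1 fell adjusted over the list alone; median 0.26, camera adjusted p = 0.0152). These included the elongation factors Eef1a1 (1.37 ± 0.12, adjusted p = 9.22e-09) and Eef2 (0.82 ± 0.10, adjusted p = 9.31e-07). The kinase Eif2ak2, which shuts translation down on double-stranded RNA, was among them (1.38 ± 0.22, adjusted p = 5.43e-05). Of 40 actin and adhesion proteins 11 rose (12 rose and 1 fell adjusted over the list alone; median 0.21, camera adjusted p = 0.0144). They were led by the pleckstrin Plek (2.24 ± 0.20, adjusted p = 1.05e-08), Zyx (1.04 ± 0.16, adjusted p = 2.74e-05) and Msn (0.75 ± 0.09, adjusted p = 5.72e-07). That list call became adjusted p = 0.0689 with an estimated correlation. Among cytosolic chaperones 4 of 21 rose, with Dnaja1 at 1.09 ± 0.17 (adjusted p = 4.30e-05) and Hspa8 at 0.81 ± 0.09 (adjusted p = 5.54e-07) (4 adjusted over the list alone; camera adjusted p = 0.324). In the pentose phosphate and NRF2 list 7 of 20 rose and 1 fell, the same counts as adjusted over the list alone. Among those that rose were the antioxidant enzymes Txnrd1 (1.25 ± 0.12, adjusted p = 1.60e-08), Prdx1 (0.93 ± 0.14, adjusted p = 2.74e-05) and Hmox1 (0.71 ± 0.12, adjusted p = 0.000152). The list was not called (camera adjusted p = 0.287), with a mean of 0.13 and a median just below 0. All named examples were higher in 6 of 6 pairs.

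Lysosomal hydrolases went the other way, with 8 of 49 lower and 41 not passing (11 fell adjusted over the list alone; median -0.31, camera adjusted p = 2.15e-06). The mannosidase Man2b1 changed by -0.76 ± 0.12 (adjusted p = 3.69e-05), the acid lipase Lipa by -0.76 ± 0.15 (adjusted p = 0.000453) and cathepsin D (Ctsd) by -0.73 ± 0.16 (adjusted p = 0.00141), each lower in 6 of 6 pairs. No mitochondrial ribosomal protein of 40 passed limma's test (3 had an unadjusted p under 0.05), while the list was lower as a whole (median -0.21, camera adjusted p = 0.023). Of 54 oxidative phosphorylation proteins 1, Sdhb, fell (-0.45 ± 0.13, adjusted p = 0.018, 6 of 6 pairs) and none passed adjusted over the list alone. The list median was -0.18 and the camera adjusted p = 0.0163, which became adjusted p = 0.0803 with an estimated correlation. Phagocytic and pattern recognition receptors split, with 5 of 27 higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.408). The LPS co-receptor Cd14 (1.83 ± 0.19, adjusted p = 8.62e-08) and the lectin Clec4d (1.97 ± 0.14, adjusted p = 6.30e-10) rose and the scavenger receptor Lrp1 fell (-0.67 ± 0.09, adjusted p = 2.79e-06), each in 6 of 6 pairs.

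Of the other lists, that of macrophage markers alone was called in the new fraction. Of 34 constitutive proteasome subunits 2 rose, Psma5 (0.69 ± 0.17, adjusted p = 0.00475) and Psmd11 (0.49 ± 0.13, adjusted p = 0.0104, but -0.08 with the deposited normalised ratios), in 6 of 6 pairs (2 adjusted over the list alone; camera adjusted p = 0.701). Of 15 glycolytic enzymes 1 rose, also adjusted over the list alone, the hexokinase Hk2 (0.62 ± 0.16, adjusted p = 0.00922, 6 of 6 pairs). The list median was 0.04 and the test leaned downward (camera adjusted p = 0.701). The 12 sterol biosynthesis enzymes gave no call by limma (2 at an unadjusted p under 0.05, none adjusted over the list alone). Their median was 0.06 and the test leaned downward (camera adjusted p = 0.701), with Hmgcs1 at 0.94 ± 0.39 (adjusted p = 0.141). The 25 replication proteins (2 at an unadjusted p under 0.05, camera adjusted p = 0.324, Dnmt1 -0.46) and the 16 histones (3 at an unadjusted p under 0.05, camera adjusted p = 0.111) gave none by limma either, nor adjusted over the list alone. Among 21 ER chaperones Hspa5 rose (0.45 ± 0.10, adjusted p = 0.00228) and Erp29 fell (-0.50 ± 0.13, adjusted p = 0.0113), each in 6 of 6 pairs and also adjusted over the list alone, with a camera adjusted p = 0.161. Markers of other cells moved too. Of 11 granulocyte proteins 3 fell (Ltf, Ngp and the chitinase-like Chi3l3 at -0.62 ± 0.11, adjusted p = 0.000303) and the haptoglobin Hp rose (1.39 ± 0.20, adjusted p = 1.60e-05). The counts were the same adjusted over the list alone (camera adjusted p = 0.0664). Of 11 macrophage markers 3 fell, Csf1r, Apoe and lysozyme Lyz2 (-0.95 ± 0.16, adjusted p = 8.84e-05), and Cd14 rose (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00186). The platelet chemokine Pf4 fell (-0.59 ± 0.12, adjusted p = 0.000638, lower in 6 of 6 pairs), the erythroid Ca2 (0.77, adjusted p = 0.608) did not pass, and no lymphocyte marker was measured often enough to test.

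In limma's test 408 of 3316 proteins differed in H/L late, 350 higher and 58 lower, and 203 of them changed at least 2-fold (190 higher, 13 lower). Without a run factor 309 passed, 96.8% of them higher, the all-protein median moved to 0.20 and that of the lysosome list to -0.14. The calls of Ttc7a, Cd97, Glul, Tnfrsf26, Lgmn, Sdhb, Psma5, Psmd11, Man2b1, Lipa, Ctsd, Lrp1, Hspa5, Erp29, Chi3l3, Lyz2 and Pf4 ended then, with the median standard error at 0.326 (main 0.277). The rises of Psma5 (0.86), Psmd11 (0.65) and Hspa5 (0.62) were larger by the shift common to all proteins, so their calls ended through the spread. With each channel centred on its own median 398 passed (74.6% higher), and with the deposited normalised ratios 554 passed (23.5% higher, all-protein median -0.48). Members passing by limma without a run factor fell from 8 to 0 for the lysosome list (6 at an unadjusted p under 0.05). They fell from 27 to 18 for the cytosolic ribosome, 12 to 8 for translation factors and 11 to 7 for actin proteins, while the medians shifted up with all proteins, to 0.69, 0.43 and 0.37. With the normalised ratios the actin (-0.27), cytosolic ribosome (-0.02) and translation factor (-0.26) medians were below 0, as all proteins shifted down to that -0.48. Without replicate 2 the count was 138 and without replicate 1 it was 214. Subtracting H/L at 0 h, a setting chosen after seeing the data, left 140 calls among 1792 proteins. It ended those of the mitochondrial ribosome, translation factor and macrophage lists (adjusted p = 0.077 each) and of the actin list (adjusted p = 0.215). Centring on the channel's own median ended the mitochondrial ribosome (adjusted p = 0.0644) and actin (adjusted p = 0.0725) calls.

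**Figure D1:**
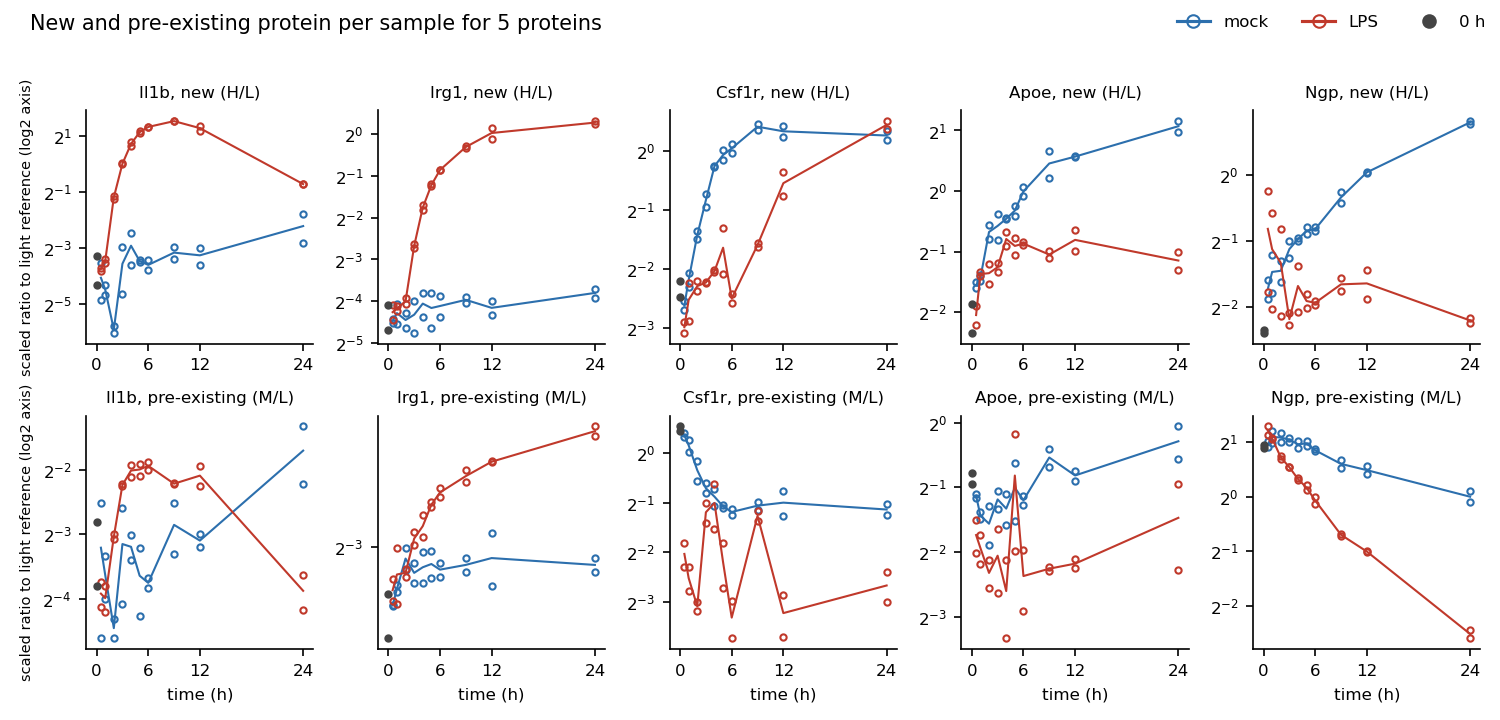
Scaled ratio to the light mix (log2 axis) against time in hours for Il1b, Irg1, Csf1r, Apoe and Ngp, new protein (H/L) above and pre-existing protein (M/L) below, with points for samples and lines for means of 2 (blue mock, red LPS, black 0 h). New Il1b reached 2.44 ± 0.222 at 12 h after LPS against 0.104 ± 0.0303 in mock cells, and pre-existing Csf1r was 0.107 ± 0.0433 against 0.50 ± 0.121.

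**Figure D2:**
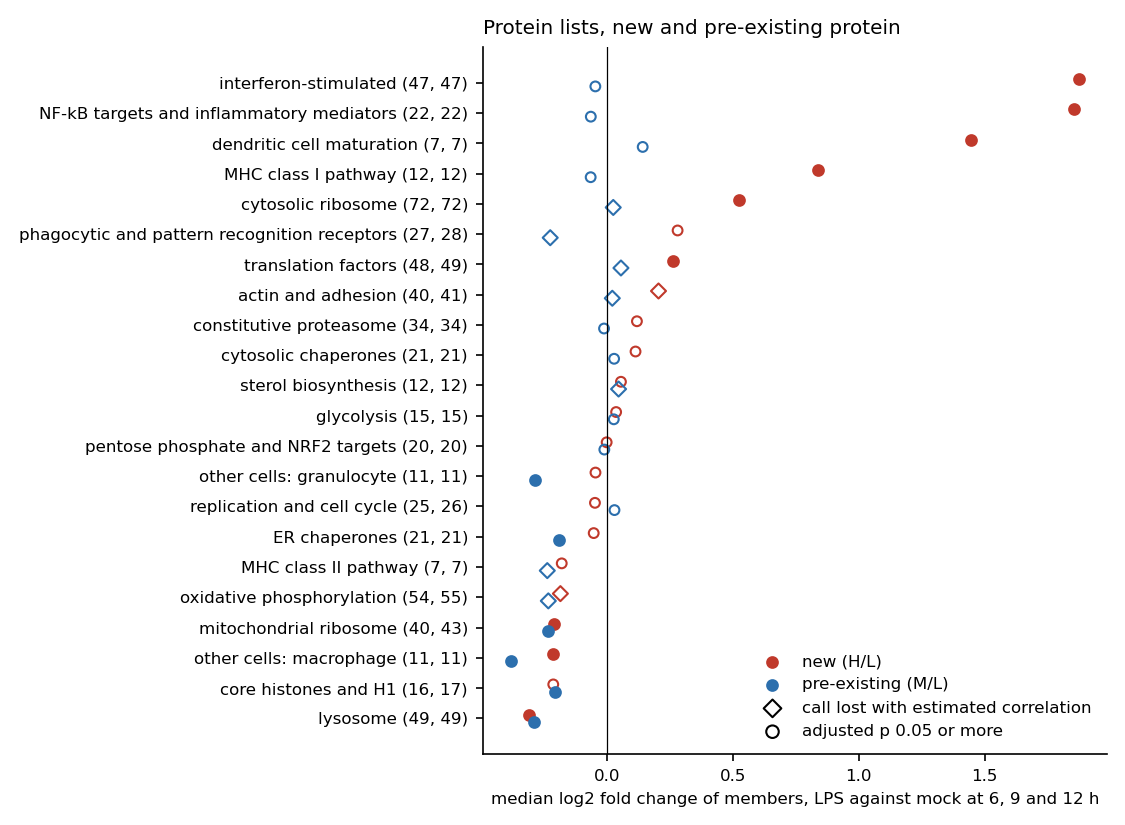
Median log2 change of each gene list over 6, 9 and 12 h in new (red) and pre-existing (blue) protein, with members measured in brackets (filled points, called; diamonds, call lost with an estimated correlation; open points, adjusted p of 0.05 or more). The interferon list sits at 1.87 in H and -0.05 in M, and the H medians of the actin, cytosolic ribosome and translation factor lists turn negative with the deposited normalised ratios, which shift all proteins (all-protein median -0.48).

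In the new fraction few proteins differed in the first hours. Over 1, 2 and 3 h new Il1b rose by 3.20 ± 0.26 (adjusted p = 4.97e-08) and the AP-1 subunit Junb by 1.35 ± 0.18 (adjusted p = 8.91e-05). Il1a rose by 1.31 ± 0.30 (adjusted p = 0.0444) and Marcksl1 by 1.16 ± 0.18 (adjusted p = 0.0012), each higher in 6 of 6 pairs. New lipoprotein lipase (Lpl), which frees fatty acids from lipoproteins, was lower in 6 of 6 pairs (-0.62 ± 0.11, adjusted p = 0.00367). Of 3223 proteins tested with limma 15 passed in H/L, 11 higher and 4 lower. With the run factor left out, 2 passed, and Il1a (1.32), Marcksl1 (1.17) and Lpl (-0.61) no longer did. The H/L counts then grew with time, from 1 protein at 0.5 h and 17 at 3 h to 93 at 6 h, 246 at 12 h and 306 at 24 h (2 samples in each arm at each time). The median H share in mock cells was 14.3% at 1 h and 15.0% at 3 h against 13.7% at 0 h. Little new protein was thus measurable early, which limits these counts. In M/L 66 proteins passed at 0.5 h (49 higher, 17 lower) and 5 at 1 h. The 0.5 h samples lie outside the early window, and the cause of those calls was not tested.

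**Figure D3:**
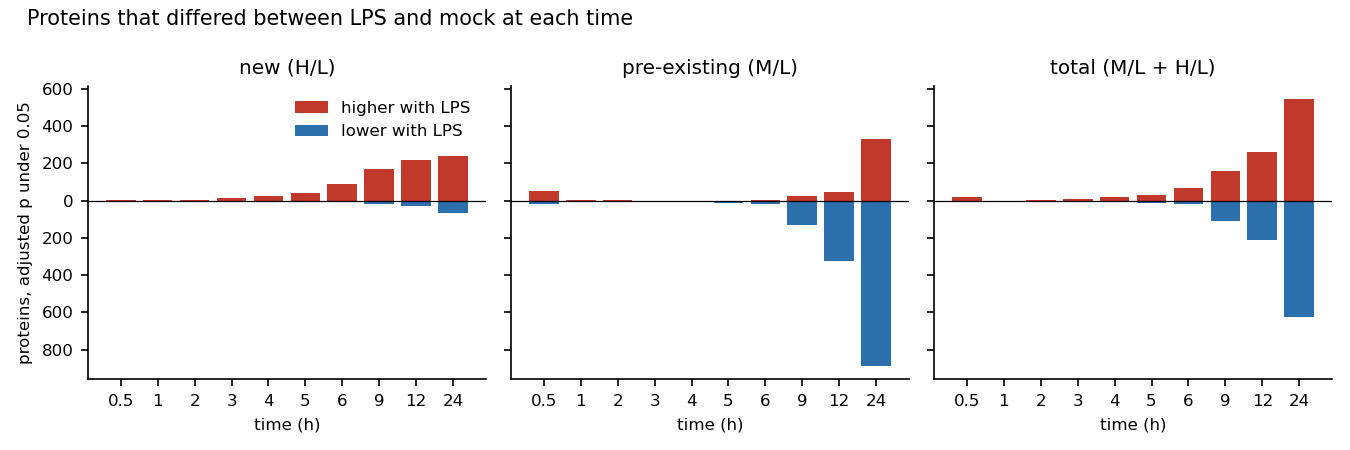
Proteins passing limma's test at each time in hours (bars up, higher in LPS, red; bars down, lower, blue) for new (H), pre-existing (M) and total (T) protein, 2 LPS against 2 mock samples per time. New protein calls rose from 1 at 0.5 h to 246 at 12 h, while pre-existing protein calls were 66 at 0.5 h, 22 at 6 h and 1215 at 24 h.

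The late effect on new protein was higher than the early one for Ccl5 and the interferon-induced Bst2 and Xaf1, among others. The difference was 4.06 ± 0.56 (adjusted p = 2.25e-05) for Ccl5, 3.49 ± 0.85 (adjusted p = 0.00974) for Bst2 and 3.41 ± 0.38 (adjusted p = 1.14e-06) for Xaf1. The late changes of these 3 were higher in 6 of 6 pairs. It was -1.16 ± 0.20 (adjusted p = 0.000316) for Mmp12 and -1.17 ± 0.29 (adjusted p = 0.0128) for Tnfaip8l2, and -2.51 ± 0.61 (adjusted p = 0.00956) for Ttc7a and -1.11 ± 0.31 (adjusted p = 0.0291) for the adhesion protein Fblim1. Cdc73, a subunit of the Paf1 transcription complex, gave the highest difference (4.08 ± 1.17, adjusted p = 0.0348). It came from a low early value (-4.05, adjusted p = 0.0252), while the late change was higher in 4 of 6 pairs. In limma's test of this difference 229 of 3186 proteins passed, 201 with a higher and 28 with a lower late effect. With no run factor 113 passed, 99.1% of them higher (all-protein median 0.21), and Mmp12, Tnfaip8l2 and Fblim1 did not.

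At 24 h (2 against 2 samples) new Ccl5 (4.64 ± 0.69, adjusted p = 3.86e-05) and Irg1 (4.08 ± 0.28, adjusted p = 4.23e-10) were highest. Next came the fatty acid activating enzyme Acsl1 (4.06 ± 0.26, adjusted p = 9.44e-11) and the nuclear body protein Sp100 (3.76 ± 0.64, adjusted p = 0.00081, a name shared by more than 1 protein group), all in 2 of 2 pairs. New Mmp12 (-3.08 ± 0.25, adjusted p = 4.16e-09) and Ngp (-2.98 ± 0.42, adjusted p = 2.30e-05) were lowest. Ltf (-2.38 ± 0.31, adjusted p = 7.27e-06) and Cd97 (-2.25 ± 0.58, adjusted p = 0.0124, not passing with no run factor at -2.01) followed, all lower in 2 of 2 pairs. Of 3310 proteins 306 passed in H/L, 240 higher and 66 lower, and with no run factor 173 passed (94.2% higher, all-protein median 0.29).

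Among proteins made before the stimulus, more were lower than higher late (468 and 121), but with the deposited normalised ratios fewer were (460 and 538). The receptor Csf1r changed by -1.55 ± 0.19 (adjusted p = 2.37e-06) in M/L late, with a scaled ratio of 0.107 ± 0.0433 after LPS and 0.50 ± 0.121 in mock cells at 12 h, against 1.41 ± 0.064 at 0 h. The inactive rhomboid Rhbdf2 (-1.78 ± 0.09, adjusted p = 1.53e-12) fell together with Adam17 (-1.30 ± 0.16, adjusted p = 4.42e-06), the sheddase it carries to the cell surface. At 12 h Rhbdf2 was at 0.223 ± 0.0263 after LPS and 0.641 ± 0.00765 in mock cells. Thrombospondin Thbs1 (-1.38 ± 0.09, adjusted p = 9.44e-11) and complement C1qb (-1.30 ± 0.08, adjusted p = 4.68e-11) fell, as did Apoe (-1.44 ± 0.28, adjusted p = 0.000637) and Ngp (-1.23 ± 0.05, adjusted p = 1.48e-14). Each of these 7 was lower in 6 of 6 pairs, and the lipid droplet protein Plin2 in 5 of 5 (-1.53 ± 0.14, adjusted p = 3.10e-07). Pre-existing Sqstm1 was higher in 6 of 6 pairs (0.81 ± 0.09, adjusted p = 1.19e-06), as were Il1b (1.17 ± 0.29, adjusted p = 0.0056; 0.85 and not passing over 9 and 12 h only) and Tbc1d5 (0.70 ± 0.13, adjusted p = 0.000459). So were the antiviral Ifitm3 (0.68 ± 0.15, adjusted p = 0.00246) and Hmgcs1, an enzyme of sterol synthesis (0.55 ± 0.08, adjusted p = 2.01e-05). The phosphatase inhibitor Arpp19, with 1 unique peptide (0.88 ± 0.16, adjusted p = 0.000516, 5 of 5 pairs) was also higher. So were the receptor Notch2 (0.75 ± 0.16, adjusted p = 0.00224) and the kinase Map4k1 (0.53 ± 0.13, adjusted p = 0.0118), both in 4 of 4 pairs. Without a run factor Rhbdf2, Thbs1, C1qb, Ngp, Plin2 and Sqstm1 still passed and Arpp19, Notch2, Ifitm3, Hmgcs1 and Map4k1 did not. From summed intensities Csf1r (-1.09), Apoe (-1.13), Adam17 (-1.04), Notch2, Tbc1d5, Hmgcs1 and Map4k1 did not pass.

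Pre-existing lysosomal proteins fell as a group. Of 49 members 35 fell and 14 did not pass (39 fell adjusted over the list alone; median -0.29, camera adjusted p = 2.82e-24). Man2b1 was at -0.32 ± 0.02 (adjusted p = 4.32e-10), the peptidase Dpp7 at -0.32 ± 0.03 (adjusted p = 3.19e-08) and progranulin Grn at -0.33 ± 0.03 (adjusted p = 1.14e-07). Of 21 ER chaperones 14 fell (17 adjusted over the list alone; median -0.19, camera adjusted p = 2.02e-06), among them Hspa5 (-0.25 ± 0.03, adjusted p = 1.14e-05) and Calr (-0.20 ± 0.03, adjusted p = 0.00013). Of 17 histones 8 were lower than in mock cells (10 adjusted over the list alone; camera adjusted p = 2.50e-06). They were led by the linker histones Hist1h1a (-1.03 ± 0.10, adjusted p = 6.07e-08), Hist1h1b (-1.03 ± 0.11, adjusted p = 4.17e-07) and Hist1h1c (-0.73 ± 0.08, adjusted p = 4.59e-07). M/L of Hist1h1b rose over time in mock cells, so its difference does not show a loss. Of 43 mitochondrial ribosomal proteins 18 fell (21 adjusted over the list alone; median -0.23, camera adjusted p = 4.48e-06), such as Mrpl41 (-0.26 ± 0.04, adjusted p = 5.98e-05). Of 55 oxidative phosphorylation proteins 25 fell (31 adjusted over the list alone; median -0.23, camera adjusted p = 7.76e-08). Uqcrc1 (-0.25 ± 0.03, adjusted p = 1.14e-05) and Sdha (-0.29 ± 0.04, adjusted p = 1.90e-05) were among them, and that list call became adjusted p = 0.0565 with an estimated correlation. Of 11 granulocyte markers 4 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 3.79e-09), with Ltf at -1.18 ± 0.06 (adjusted p = 1.33e-12) and lipocalin Lcn2 at -1.04 ± 0.14 (adjusted p = 1.14e-05). Of 11 macrophage markers 7 fell (also adjusted over the list alone; camera adjusted p = 3.79e-09), with Lyz2 at -0.37 ± 0.02 (adjusted p = 9.44e-11), and Pf4 fell too (-0.83 ± 0.15, adjusted p = 0.00021) while Ca2 (-0.12) did not pass. Every example that fell was lower in 6 of 6 pairs. With the run factor left out, Hist1h1b and Ltf alone of these examples still passed. All proteins shifted up then, from a median of -0.02 to 0.15, and the medians of the lysosome (-0.12), ER chaperone (-0.02), oxidative phosphorylation (-0.07) and mitochondrial ribosome (-0.08) lists with them. With this shift and a wider spread, by limma 0 members passed of the lysosome and ER chaperone lists (1 each at an unadjusted p under 0.05) and 0 of the oxidative phosphorylation and mitochondrial ribosome lists (0 each at an unadjusted p under 0.05). Of the histones 3 passed, of the granulocyte markers 2 and of the macrophage markers 3.

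In the MHC class II pathway 4 of 7 pre-existing proteins fell (also adjusted over the list alone), with the invariant chain Cd74 at -0.75 ± 0.19 (adjusted p = 0.00702) and cathepsin S (Ctss) at -0.24 ± 0.05 (adjusted p = 0.00052). The list call (camera adjusted p = 0.0358) became adjusted p = 0.073 with an estimated correlation. Of 28 phagocytic receptors 8 fell (9 adjusted over the list alone), among them Axl (-0.81 ± 0.09, adjusted p = 4.17e-07) and the mannose receptor Mrc1 (-0.51 ± 0.09, adjusted p = 0.000205). Its call (camera adjusted p = 0.0453) became adjusted p = 0.0858 with the replicate block and adjusted p = 0.534 with an estimated correlation. The cytosolic ribosome (5 of 72 rose, 1 fell, 1 and 1 adjusted over the list alone; adjusted p = 0.00492) held Rps6 at 0.41 ± 0.09 and Rpl14 at -0.31 ± 0.06. Its upward call became adjusted p = 0.536 with an estimated correlation. The upward call of translation factors (7 of 49 rose, 3 fell, also adjusted over the list alone, Eif4g1 0.19 ± 0.05; adjusted p = 0.00275) became adjusted p = 0.382 with an estimated correlation. That of actin proteins (5 of 41 rose, 1 fell, also adjusted over the list alone, Zyx 0.17 ± 0.04; adjusted p = 0.00859) became adjusted p = 0.503 with an estimated correlation. That of sterol enzymes (Hmgcs1 rose and Lbr fell of 12, also adjusted over the list alone; adjusted p = 0.0358) became adjusted p = 0.073 with an estimated correlation.

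Pre-existing interferon-stimulated proteins were not called as a group (3 of 47 rose and 5 fell, 2 and 5 adjusted over the list alone; camera adjusted p = 0.797). The ubiquitin ligase Trim25 (-0.63 ± 0.06, adjusted p = 1.44e-07) and Parp12 (-0.60 ± 0.09, adjusted p = 4.14e-05) were lower in 6 of 6 pairs. Of 22 NF-kB targets 5 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.366). Among them Irg1 was higher (0.53 ± 0.06, adjusted p = 1.15e-06) and the NF-kB subunit Rela lower (-0.42 ± 0.05, adjusted p = 1.33e-06) in 6 of 6 pairs. The list median (-0.06) and mean (0.01) differed in sign. In the MHC class I pathway 3 of 12 fell, also adjusted over the list alone, with B2m at -0.33 ± 0.08 (adjusted p = 0.00359) and Erap1 at -0.29 ± 0.05 (adjusted p = 6.21e-05), but 0.01 from summed intensities (camera adjusted p = 0.366). Cytosolic chaperones (2 rose and 2 fell of 21; camera adjusted p = 0.142) held the mitochondrial Hspd1 at -0.25 ± 0.04 and Hsph1 at 0.22 ± 0.04. Hk2 was the glycolytic enzyme of 15 that fell (-0.29 ± 0.07, adjusted p = 0.0071, 6 of 6 pairs; camera adjusted p = 0.19). Srxn1 (-0.14) and catalase Cat (-0.15) were the 2 of 20 pentose phosphate and NRF2 proteins that fell (camera adjusted p = 0.797), and with no run factor the shift of all proteins put them at 0.03 and 0.02. Of 26 replication proteins 1 rose and 2 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.366), with the proliferation marker Mki67 at -0.61 ± 0.09 (adjusted p = 4.82e-05). No constitutive proteasome subunit of 34 (1 at an unadjusted p under 0.05; camera adjusted p = 0.456) and no maturation protein of 7 (1 at an unadjusted p under 0.05; camera adjusted p = 0.222) passed limma's test.

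In M/L late 589 of 3432 proteins passed limma's test, 121 higher and 468 lower, and 22 changed at least 2-fold (2 higher, 20 lower). These calls rested on the run factor. With none, 20 passed (4 higher, 16 lower), 19 of them among the 589. Of the 589, 54 had the opposite sign. The median standard error rose from 0.0747 to 0.243 and the all-protein median was 0.15. The LPS 12 h run of replicate 2 stood apart, with a run factor of 0.69 against -0.05 in its mock partner. In settings chosen after seeing the data and without the run factor, leaving that run out gave 19 calls and an all-protein median of -0.05. The replicate block gave 436 (377 higher, 59 lower; median standard error 0.0943), and both together gave 608 (252 higher, 356 lower). Of the 589 calls, 177 came back on the same side with the block (53 had the opposite sign) and 442 with both, so the spread between replicates and the shift of that 1 run each took part in the loss. With each channel centred on its own median 591 passed, 37.6% of them higher against 20.5% in the main setting, and with the deposited normalised ratios 998 passed, 53.9% higher. Fitting the late samples alone gave 303, and leaving out replicate 2 or replicate 1 gave 33 or 48. Early after LPS (1, 2 and 3 h) 12 of 3397 pre-existing proteins passed, all lower. They were led by Csf1r (-1.97 ± 0.19, adjusted p = 3.12e-07) and the nucleosome-binding Hmgn1 (-1.07 ± 0.07, adjusted p = 1.46e-09). Rhbdf2 (-0.82 ± 0.09, adjusted p = 6.81e-06) and Rtn4 (-0.66 ± 0.06, adjusted p = 3.12e-07) followed, each lower in 6 of 6 pairs. Csf1r alone of these 4 kept its call with no run factor, where 2 passed. With the replicate block 30 passed early (7 higher, 23 lower).

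At 24 h 1215 of 3408 pre-existing proteins passed limma's test, 329 higher and 886 lower. Impdh1, an enzyme of guanine nucleotide synthesis (-4.03 ± 0.35, adjusted p = 9.75e-09), and the protease inhibitor Cst3 (-3.55 ± 1.00, adjusted p = 0.0109) were lowest. Hist1h1b (-2.98 ± 0.19, adjusted p = 1.91e-11) and the actin-binding Lasp1 (-2.81 ± 0.30, adjusted p = 2.94e-07) came next. Arpp19 (1.78 ± 0.24, adjusted p = 6.75e-06) and the phosphatase inhibitor Ppp1r14b (1.40 ± 0.12, adjusted p = 2.73e-09) were highest. Nucks1 (1.39 ± 0.14, adjusted p = 5.17e-08, lost with no run factor) and Serpinb6 (1.39 ± 0.13, adjusted p = 8.81e-09) followed. Each difference had the same sign in 2 of 2 pairs. With no run factor 23 passed (all-protein median 0.17), and with each channel centred on its own median 1341 passed, 49.8% of them higher against 27.1%.

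Total protein (M/L plus H/L) rose late for proteins that also rose most in the new fraction. Il1b rose by 3.81 ± 0.22 (adjusted p = 3.21e-12), Il1a by 2.95 ± 0.20 (adjusted p = 3.78e-11) and Cd40 by 2.77 ± 0.28 (adjusted p = 6.30e-08). Irg1 rose by 2.42 ± 0.08 (adjusted p = 6.14e-17) and Bst2 by 2.15 ± 0.35 (adjusted p = 6.03e-05) (1.77 and not passing from summed intensities). Ifi47 rose by 2.04 ± 0.09 (adjusted p = 2.81e-14) and Ccl5 by 2.04 ± 0.18 (adjusted p = 4.00e-09), each of these 7 in 6 of 6 pairs. Ifi204 was higher in 5 of 5 (1.90 ± 0.19, adjusted p = 4.23e-07). Csf1r (-1.62 ± 0.11, adjusted p = 3.09e-11), Apoe (-1.30 ± 0.12, adjusted p = 8.31e-09) and Ngp (-1.28 ± 0.05, adjusted p = 1.10e-15) were lowest. Mmp12 (-1.22 ± 0.08, adjusted p = 3.90e-11) and Ltf (-1.19 ± 0.07, adjusted p = 1.24e-11) fell too. The histone Hist1h3b (-1.07 ± 0.25, adjusted p = 0.00307) and Lpl (-1.0 ± 0.11, adjusted p = 1.08e-07, but -0.11 and not passing from summed intensities) followed. These 7 were lower in 6 of 6 pairs, and Lasp1 in 4 of 4 (-1.17 ± 0.28, adjusted p = 0.00386; -0.93 and not passing from summed intensities). Of 3316 proteins 657 passed limma's test, 339 higher and 318 lower, 66 of them at least 2-fold (58 higher, 8 lower). Without a run factor 117 passed (91.5% higher, all-protein median 0.17), and with the deposited normalised ratios 659 did (23.5% higher, all-protein median -0.27). Without replicate 2 the count was 148 and without replicate 1 it was 221.

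In total protein the interferon-stimulated list rose (37 of 47, 38 adjusted over the list alone; median 0.93, camera adjusted p = 6.97e-42), as did NF-kB targets (18 of 22, 19 adjusted over the list alone; median 1.07, adjusted p = 4.20e-42). Maturation proteins rose (5 of 7, 7 adjusted over the list alone; adjusted p = 0.000169). So did the MHC class I pathway (7 of 12, 7 higher and 1 lower adjusted over the list alone; adjusted p = 3.08e-05), with B2m at 0.69 ± 0.05 (adjusted p = 2.72e-11) and H2-K1 at 0.86 ± 0.10 (adjusted p = 2.46e-07). Lysosomal proteins (35 of 49 fell, 37 adjusted over the list alone; median -0.30, adjusted p = 1.09e-17) were lower. So were oxidative phosphorylation (22 of 54, 28 adjusted over the list alone; adjusted p = 2.93e-06) and the mitochondrial ribosome (12 of 40, 13 adjusted over the list alone; adjusted p = 0.000756). Of 16 histones 8 fell (10 adjusted over the list alone; adjusted p = 4.52e-05). ER chaperones were lower too (13 of 21, 17 adjusted over the list alone; adjusted p = 5.86e-05), but with adjusted p = 0.054 with an estimated correlation. Granulocyte (4 of 11 fell, 2 rose, also adjusted over the list alone; adjusted p = 3.15e-05) and macrophage markers (7 of 11 fell, 1 rose, also adjusted over the list alone; adjusted p = 3.15e-05) were lower beside them. Pf4 fell (-0.69 ± 0.09, adjusted p = 1.87e-06, 6 of 6 pairs). With the run factor left out, all proteins shifted to a median of 0.17 and the granulocyte list to 0.07. By limma, with a median standard error of 0.239 (main 0.0854), 0 members then passed of the lysosome, ER chaperone (1 each at an unadjusted p under 0.05), mitochondrial ribosome (2) and oxidative phosphorylation lists (0). Histones had 3 lower, and granulocyte and macrophage markers 2 each.

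In total protein the upward call of the cytosolic ribosome (11 of 72 rose, 1 fell, also adjusted over the list alone; adjusted p = 0.0198) became adjusted p = 0.576 with an estimated correlation. That of translation factors (14 of 48 rose, 1 fell, 15 and 1 adjusted over the list alone; adjusted p = 0.00348; median -0.11 with the normalised ratios, which shift all proteins) became adjusted p = 0.198 with an estimated correlation. That of actin proteins (10 of 40 rose, also adjusted over the list alone, Plek 1.01 ± 0.05; adjusted p = 0.0116; median -0.14 with them) became adjusted p = 0.324 with an estimated correlation. Subtracting H/L at 0 h ended the mitochondrial ribosome, cytosolic ribosome and actin calls (adjusted p = 0.108, 0.177 and 0.0935). The MHC class II pathway (3 of 7 fell; adjusted p = 0.0818) was called with the replicate block alone (adjusted p = 0.0485). Phagocytic receptors (5 of 27 rose and 4 fell; adjusted p = 0.473) held Clec4d at 1.48 ± 0.09 and Cd14 at 0.93 ± 0.07. Pentose phosphate and NRF2 proteins (5 of 20 rose, 1 fell; adjusted p = 0.268) and cytosolic chaperones (5 rose, 2 fell; adjusted p = 0.256) were not called. Neither were sterol enzymes (1 rose, 1 fell; adjusted p = 0.543) or replication proteins (1 rose, 1 fell; adjusted p = 0.852). Proteasome subunits (1 rose; adjusted p = 0.852) and glycolysis (no member passed limma's test, 1 at an unadjusted p under 0.05; adjusted p = 0.753) were not called.

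Early total protein was higher for Il1b (2.10 ± 0.22, adjusted p = 1.70e-06), Junb (0.85 ± 0.16, adjusted p = 0.00397) and the TNF-induced Tnfaip2 (0.55 ± 0.06, adjusted p = 1.20e-05), and for Marcksl1 (0.44 ± 0.07, adjusted p = 0.00058), each in 6 of 6 pairs. It was lower for Csf1r (-1.55 ± 0.11, adjusted p = 1.74e-09), Hmgn1 (-1.01 ± 0.09, adjusted p = 1.53e-07) and Rpl34 (-0.60 ± 0.11, adjusted p = 0.00397) in 6 of 6 pairs. Rhbdf2 was lower in 4 of 4 (-0.77 ± 0.11, adjusted p = 0.000328). Of 3223 proteins 27 passed limma's test early, 11 higher and 16 lower. With no run factor 3 passed, with Il1b and Csf1r alone of these 8 among them. At 24 h total Cd40 (2.93 ± 0.49, adjusted p = 4.46e-05) and Irg1 (2.91 ± 0.14, adjusted p = 6.52e-14) were highest. Sp100 (2.76 ± 0.24, adjusted p = 1.57e-07) and the predicted gene product Gm4902 (2.75 ± 0.44, adjusted p = 3.48e-05) followed. Impdh1 (-3.85 ± 0.38, adjusted p = 1.18e-07) and Hist1h1b (-2.85 ± 0.20, adjusted p = 9.07e-11) were lowest, followed by Ngp (-2.79 ± 0.08, adjusted p = 1.23e-17) and Hist1h1c (-2.59 ± 0.15, adjusted p = 3.48e-12), all in 2 of 2 pairs. Of 3310 proteins 1169 passed at 24 h, 543 higher and 626 lower, against 111 with no run factor (82.9% higher, all-protein median 0.24).

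The H/M ratio of a protein needs neither the light mix nor a run factor. Late after LPS it rose by 4.19 ± 0.34 (adjusted p = 1.15e-08) for Mndal (4 of 4 pairs). In 6 of 6 pairs it rose by 4.19 ± 0.41 (adjusted p = 2.28e-08) for Il1a, 3.85 ± 0.50 (adjusted p = 2.68e-06) for Ccl5 and 3.59 ± 0.12 (adjusted p = 6.43e-17) for Irg1. It was lower for Plcb3 (-1.59 ± 0.46, adjusted p = 0.0204; -0.73 and not passing from summed intensities), Tnfaip8l2 (-1.17 ± 0.19, adjusted p = 4.96e-05) and Rab11fip5 (-0.92 ± 0.26, adjusted p = 0.0191) in 6 of 6 pairs. For Tnfrsf26 it was lower in 5 of 5 (-0.85 ± 0.21, adjusted p = 0.0119; -0.95 and not passing from summed intensities). Of 3316 proteins 412 passed limma's test, 378 higher and 34 lower. With the deposited normalised ratios 432 passed (29.4% higher, all-protein median -0.45). Without replicate 2 the count was 177 and without replicate 1 it was 227.

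Some proteins had an H/L ratio mostly on 1 side. At 6, 9 and 12 h, 11 proteins had one in at least 5 of 6 LPS samples and at most 1 of 6 mock samples. These were the chemokines Cxcl10 and Cxcl2, the pattern recognition protein Ptx3, the transcription factor Cebpd, the receptor tyrosine kinase Met, the integrin Itga4, and Otud4, Eif2b4, Igsf8, Mapk1ip1l and Polr2h. The reverse held for 5 proteins, the neutrophil collagenase Mmp8, the neutrophil surface protein Cd177, Macf1, Snx8 and Mrpl33. Their total of 16 compared with at most 15, and a median of 9, among the other ways of swapping treatment within pairs (32 in all, the real one included). No fold is given, since a missing ratio is not a measured level.

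In mock cells Csf1r, a secreted phospholipase and a pore-forming immune protein were among the proteins replaced fastest. The half-time of replacement, from the growth of the H share between 0.5 and 12 h, was 6.21 ± 0.674 h for the adaptor Sdcbp (syntenin), 6.23 ± 0.60 h for Csf1r and 6.41 ± 1.04 h for the dipeptidase Dpep2. It was 6.48 ± 1.78 h for Slfn2, 6.59 ± 0.493 h for the phospholipase Pla2g7 and 7.02 ± 0.386 h for the pore-forming Mpeg1 (SD, n = 2 replicates). The slowest with a slope past the threshold included the mitochondrial Mdh2 (313 ± 43.9 h) and Phb (290 ± 0.38 h), and the glycolytic Pkm2 (285 ± 97.6 h). The replicates of Cox5a (555 ± 561 h), Gm5483 (467 ± 389 h) and Hmgb2 (372 ± 274 h) differed widely. Of 3459 proteins 1226 had a slope below 0 and 13 a slope above 0 in limma's test. The half-time at the median slope was 120 h (105 and 141 h in the replicates) and at the 10th percentile of slopes 28.2 h. It was 25.1 h with no intercept and 68.7 h from summed intensities. Replicate slopes correlated across proteins with Pearson's r = 0.194 and Spearman's rho = 0.315 (proteins are not independent replicates), so the half-times of slow proteins are imprecise.

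By list, phagocytic receptors (18 of 25 with a slope below 0, also adjusted over the list alone; camera adjusted p = 7.82e-13) were replaced faster than other proteins, with Sirpa at 16.3 ± 0.576 h and Itgam at 32.9 ± 1.08 h. The MHC class II pathway (7 of 7, also adjusted over the list alone; adjusted p = 1.40e-05) held Cd74 at 8.35 ± 0.0431 h and H2-Ab1 at 16.1 ± 1.87 h. The pentose phosphate and NRF2 list (15 of 19, 17 adjusted over the list alone; adjusted p = 9.50e-08) held Hmox1 at 11.5 ± 0.0693 h and Srxn1 at 14.3 ± 0.0367 h. MHC class I (5 of 12, also adjusted over the list alone; adjusted p = 0.0161; B2m 8.41 ± 0.532 h) was called faster as well. Its median slope (-0.00797) was no steeper than that of all proteins (-0.0083), while its mean was -0.0313, so the call rests on some fast members. Granulocyte (11 of 15, 13 adjusted over the list alone; adjusted p = 0.00184; Ngp 21.7 ± 0.181 h) and macrophage proteins (7 of 12, also adjusted over the list alone; adjusted p = 0.0065; C1qb 7.04 ± 0.158 h) were called faster too. The calls of the lysosome (28 of 49, 30 adjusted over the list alone; adjusted p = 0.014) and actin lists (29 of 40, 31 adjusted over the list alone; adjusted p = 0.00747) became adjusted p = 0.247 and adjusted p = 0.345 with an estimated correlation. The actin median slope (-0.00723) was no steeper than that of all proteins either. The mitochondrial ribosome (4 of 42 with a slope below 0, 0 adjusted over the list alone; adjusted p = 0.00616) and histones (1 of 16 above 0, 0 adjusted over the list alone; adjusted p = 0.014) were replaced more slowly than other proteins. Interferon-stimulated proteins (8 of 47 below 0, 1 above; adjusted p = 0.0316) were called in the slower direction on the moderated t. Their median slope (-0.00967) was steeper than that of all proteins (-0.0083), so slower replacement is not shown. The call became adjusted p = 0.369 with an estimated correlation.

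No call was made for the slopes of NF-kB targets (adjusted p = 0.829), maturation proteins (adjusted p = 0.303), cytosolic ribosome (adjusted p = 0.0916), oxidative phosphorylation (adjusted p = 0.0742), proteasome (adjusted p = 0.494), or glycolysis (adjusted p = 0.829). The same held for sterol enzymes (adjusted p = 0.912), translation factors (adjusted p = 0.829), replication proteins (adjusted p = 0.624), ER chaperones (adjusted p = 0.991) and cytosolic chaperones (adjusted p = 0.252). With H/L at 0 h subtracted, the MHC class I (adjusted p = 0.230), mitochondrial ribosome (adjusted p = 0.171), histone (adjusted p = 0.245), granulocyte (adjusted p = 0.0838) and macrophage (adjusted p = 0.0758) slope calls ended. Centring on each channel's median ended those of MHC class I (adjusted p = 0.0978) and the mitochondrial ribosome (adjusted p = 0.0549).

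LPS changed the replacement slope of 464 of 3342 proteins in limma's test, 406 toward faster and 58 toward slower replacement. The slope (log2 of the M share per hour, more negative when faster) changed by -0.117 ± 0.00944 for H2-K1 (adjusted p = 9.38e-12), and -0.141 ± 0.0138 for Marcksl1 (adjusted p = 5.40e-10). It changed by -0.065 ± 0.0079 for Sdcbp (adjusted p = 5.76e-08). In the direction of slower replacement it changed by 0.0207 ± 0.00355 for Lipa (adjusted p = 2.83e-05), 0.0171 ± 0.00258 for Lyz2 (adjusted p = 3.59e-06) and 0.00848 ± 0.00199 for Man2b1 (adjusted p = 0.00189). The half-time at the median slope was 109 h after LPS. A higher share of new protein gives a steeper slope whether a protein is made faster or lost faster. A lower share gives a flatter slope in the same way, also where less new protein is made. New Lipa, Lyz2 and Man2b1 were lower late, as were pre-existing Lyz2 and Man2b1, so their flatter slopes do not show that old protein was spared. With no intercept 268 proteins passed, and with the 24 h samples added 796. Without replicate 2 the count was 253.

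The H channel was not empty before heavy label was given. At 0 h 3910 and 3882 proteins had an H/L ratio in the replicates, with a median H/M of 0.158 ± 0.0102 (n = 2). The median H share of M plus H was 13.7% at 0 h, 20.6% in mock and 21.7% in LPS cells at 12 h, and 29.4% ± 0.101 in mock and 31.7% ± 1.44 in LPS cells at 24 h (SD, n = 2). For Il1b the scaled H/L was 0.0752 ± 0.0365 at 0 h, close to the mock value at 12 h, and for Csf1r it was 0.199 ± 0.0264.

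Before stimulation the cells held abundant actin-binding and calcium-binding proteins. By the share of summed iBAQ, thymosin Tmsb4x made up 4.34% ± 1.67 in the AspN digest and 3.47% ± 0.332 in the LysN digest, and S100a9, a calcium-binding protein of myeloid cells, 4.34% ± 0.201 and 2.03% ± 0.591 (SD, n = 2). The granulocyte list made up 7.99% ± 0.136 in AspN, 3.81% ± 0.756 in LysN and 4.83% ± 0.195 in the M channel of trypsin at 0 h. Shares of the macrophage (1.68%, 2.06% and 1.81%), lysosome (3.19%, 3.59% and 2.55%) and MHC class II lists (0.968%, 0.747% and 0.179%) followed in the same order. Across 2434 proteins log2 iBAQ in AspN and LysN correlated with Spearman's rho = 0.860 (Pearson's r = 0.873), and with trypsin at rho = 0.834 and 0.844. Proteins are not independent replicates, and the digests come from separate tables, so no test was made between them.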

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

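The test of the late against the early effect was planned, as were its splits. The LPS effect on new protein at 6, 9 and 12 h differed from that at 1, 2 and 3 h for 229 proteins in limma's test of the difference. Ccl5, Bst2 and Xaf1 were among the highest differences, at 4.06, 3.49 and 3.41, and Ttc7a (-2.51) and Mmp12 (-1.16) among the lowest. Of 100 ways to swap treatment within pairs, the real one included, 5 gave at least as many calls and the highest other gave 263, so chance cannot be excluded for this count. Swaps of early pairs alone keep the late effect, which is part of the difference tested.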

How the results depend on the processing

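The 0 h subtraction, the fits without 0.5 h samples, the block at each time, the 0 h replicates alone, and no run factor with the block or 1 run left out were chosen after seeing the data. Of 146 values of counts and summaries under alternatives (samples left out not counted), 107 stayed within 1.5 times the main count or within 1 SD of the main value. Of 306 single-protein results (173 proteins, 7187 alternative values), 6358 values kept direction and side of the threshold, 816 kept direction and no longer passed, and 13 changed sign. For 91 results every alternative stayed on the same side. The limits are depth (8 to 10 peptide pairs behind a typical ratio), 2 samples per group, and the run factor, on which the M/L calls depend.

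With no run factor calls fell from 589 to 20 for M/L late, 12 to 2 for M/L early, 1215 to 23 for M/L at 24 h, 657 to 117 for total late, 27 to 3 for total early, 1169 to 111 for total at 24 h, 15 to 2 for H/L early, 306 to 173 for H/L at 24 h, and 229 to 113 for late minus early. With no run factor and the LPS 12 h run of replicate 2 left out, H/L gave 199, M/L 19 and total 86 calls late. With no run factor and the replicate block M/L gave 436 and total 810, 86.5% and 94.8% of them higher, and with that run left out too 608 and 716, 41.4% and 69.4% higher. The deposited normalised ratios gave 998 for M/L late. Summed intensities gave 269 for H/L (main 408), 241 for M/L, 306 for total and 255 for H/M (main 412) late. The late samples alone gave 303 for M/L late. With H/L at 0 h subtracted H/L gave 140, total 420 and H/M 132 calls. Part of that fall came from the 1792 proteins tested then, which left 100, 205 and 95 of the main calls untested. Without the run factor the median standard error of M/L was 0.243 (main 0.0747), and 0.0943 with the block. Of the 589 main M/L calls 177 then came back on the same side, and 442 with that run left out too, so spread and the shift of that run both took part. Of the 657 main total calls late, 381 came back on the same side without the run factor but with the block (34 had the opposite sign). With that run left out too, 543 came back. Spread and the shift of that run thus took part in the late fall of total protein as well. For the remaining falls the cause was not tested.

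The replicate block gave 30 calls for M/L early (main 12). At single times it moved M/L from 66 to 219 (0.5 h), 5 to 46 (1 h), 5 to 8 (2 h), 13 to 20 (5 h), 22 to 35 (6 h) and 154 to 301 (9 h), and total from 21 to 92 (0.5 h) and 4 to 12 (1 h). The block ended the late M/L call of the phagocytic list (adjusted p = 0.0858), made that of total MHC class II (adjusted p = 0.0485), and changed no other call of a named protein or list.

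For replacement, the half-time at the median slope of 120 h became 25.1 h with no intercept and 68.7 h from summed intensities. The slopes below 0 rose from 1226 to 3435 with no intercept, which counts the H signal at 0 h as new protein, and to 2280 with 24 h added. The LPS difference gave 268 with no intercept and 796 with 24 h added (main 464). Proteins with H/L mostly in LPS samples were 0 at 6 of 6 against 0 of 6 and 104 at 4 against 2 (main 11), and mostly in mock samples 0 and 76 (main 5), a rule whose own construction sets its count. The AspN and LysN rank correlation of 0.860 was 0.878 with at least 2 unique peptides.

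The shift common to all proteins without the run factor (all-protein median -0.02 to 0.15) put M/L late of Psmb10 (0.069), Srxn1 (0.026), Cat (0.021) and Eif4a3 (0.0077) above 0. Other values changed sign with the cause not tested. With the normalised ratios, where all proteins shifted down, they were for H/L late Psmd11 (-0.080), Hsp90ab1 (-0.066) and Cct3 (-0.18) and for total late Rps6 (-0.16) and Cdk6 (-0.15). From summed intensities they were for M/L late Oasl1 (0.36), Erap1 (0.0068) and Mrpl40 (0.16) and for total late Mrpl40 (0.049).

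Without each replicate or late sample in turn, counts ranged from 138 to 389 for H/L late, 33 to 596 for M/L late, 148 to 692 for total late and 177 to 376 for H/M late. The lowest values came without replicate 2 (without replicate 1, 214, 48, 221 and 227). That leaves 1 sample per group, assumed to vary like the others. Without single late samples the lowest were 354, 462, 556 and 342. Slopes below 0 ranged from 829 to 830, the half-time from 105 to 141 h, LPS slope differences from 253 to 357, median H/M at 0 h from 0.151 to 0.166, and the rank correlation of digests from 0.840 to 0.845.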

Other observations

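The tests of the medium form and of the light reference at 0 h, both tests of the M/L rise and the test of loading for granulocyte proteins were chosen after the result was seen, and the proteins of the first 2 paragraphs after their values were seen. The linker histone Hist1h1b parted between treatments in the pre-existing fraction. Its scaled M/L was 0.54 ± 0.062 at 0 h, 1.62 ± 0.0362 in mock cells at 12 h and 0.674 ± 0.0291 after LPS at 12 h (SD, n = 2), so the late difference of -1.03 ± 0.11 (adjusted p = 4.17e-07) came with a rise over time in mock cells. M marks protein made before the switch, so by the design such a rise is not a gain of that protein. What raised the ratio was not tested, and the M/L and total differences of Hist1h1b, late and at 24 h, carry that doubt. New prostaglandin synthase Ptgs2 rose by 2.82 ± 0.36 (adjusted p = 2.47e-06) and the nitric oxide synthase Nos2 by 1.92 ± 0.23 (adjusted p = 6.56e-07) late, each in 6 of 6 pairs.

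Some proteins had other values at 24 h than at 6 to 12 h. New Csf1r was at 0.18 at 24 h (adjusted p = 0.849) after -1.81 late, so its late call had no counterpart at the end of the course, a difference that was not tested. Pre-existing Il1b was 1.17 late and -2.13 at 24 h (adjusted p = 0.0018). For Rhbdf2 pre-existing protein was -1.10 at 24 h while total protein was 0.85 (adjusted p = 0.00029). New Apoe was -2.22 at 24 h (adjusted p = 7.2e-08) and new Il1b 1.59 (adjusted p = 0.026).

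H signal was present at 0 h, before heavy label (median H/M 0.158), and depended on intensity, with H/M at 0.0922 and 0.0924 in the replicates for the 500 most intense proteins and 0.185 and 0.167 for the others. The replicate difference of log2 H/L (0.337) lay within 0.15 of that of log2 M/L (0.482), a gap of 0.145, as M read as H would give, though the bound was barely met and set after the values were seen. Proteins nearly free of M (M/L under 0.2, 42 proteins) had 0.851 times the H/L of those with M/L over 0.5 (0.110 against 0.129), as light signal read as H would give. The tenth of proteins replaced fastest lay 0.599 (log2) above the others in H/M at 0 h (0.221 against 0.146), as early uptake would give in a test written before the result was seen. Contaminant groups had a median H/L of 0.132 and a median M/L of 0.135 over all their values at 0 h. Of these groups 50 had any H/L and 38 had it in both samples, so both medians need not cover the same groups. If contaminants carry no label, these medians argue against the medium form and uptake as the whole cause. With a signal that depends on intensity this excludes none of the 3 explanations. They are not exclusive, and no biological explanation was tested.

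For 12 proteins called higher in H/L at 3 h and 12 h, the M/L change was a median of 0.135 of the H/L rise at 3 h and -0.00822 at 12 h, with M/L up in 9 at 3 h and no M/L call upward then by limma (6 calls, all lower; 145 at an unadjusted p under 0.05). For Il1b the share was 0.108 and 0.0506, for Irg1 0.161 and 0.0607, and for Sqstm1 0.224 and 0.123. The share was higher at 3 h for 11 of 12, with a median paired difference of 0.168 (two-sided exact sign test p = 0.00635). These proteins come from the same runs and are not independent replicates, so that p does not measure the spread between samples. The H/L rise that divides the share was often smaller at 3 h than at 12 h (Il1b 0.922 and 2.33, Irg1 0.107 and 0.965). A small M/L difference then weighs more at 3 h. For Junb (0.728 and 0.604) and Tnfaip2 (0.657 and 0.453) the rise was larger at 3 h. A fixed share of H read as M (0.135) and medium-labelled amino acids still in use early (0.168) cannot be told apart, because later loss of M can hide a fixed share and 1 of 9 proteins fell below its 3 h share, fewer than the proportion set to exclude it. Protein made before the switch and spared from loss after LPS was not tested.

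Granulocyte proteins were lower with LPS in total protein at 24 h (Ngp -2.79, Ltf -2.38, Chi3l3 -0.64), but Lcn2 was at 0.25 and Hp at 2.04. The smaller late fall of Ngp and Ltf in total protein was still -1.02 without the run factor or with own-median centring. Those settings put the all-protein median at 0.17 and 0.006, so they could not have removed a fall of that size. The falls thus do not come from the choice among these scalings, and other differences in loading were not tested. Summed intensities, not part of this test, ended the late calls of new Ngp and Ltf. Fewer granulocytes would lower cytosolic S100a8 and S100a9 too, which were at -0.46 (adjusted p = 0.0052) and -0.12 (adjusted p = 0.151), and the smaller of these was 0.192 of the median granule protein's fall. Late, S100a8 was at 0.01 (adjusted p = 0.951) and S100a9 at 0.15 (adjusted p = 0.00456) with Ngp at -1.28 and Ltf at -1.19, so they did not fall together then. At 24 h, however, new S100a8 (-1.07, adjusted p = 0.0175) and new S100a9 (-1.26, adjusted p = 0.0015) were lower. Total Mpo was lower too (-0.93, adjusted p = 0.0229), while total Epx, Prg2 and Padi4 did not pass. Fewer granulocytes cannot be told apart from regulation of the granule proteins, because these values go both ways. S100a8 and S100a9 also lay on different sides of the bounds set in advance at 24 h, the time those bounds name. Those bounds used the median of 5 granule proteins, which was the value of Chi3l3 (-0.64). Lcn2 and Hp, which were not lower, counted among the 5. Against the falls of Ngp and Ltf, both S100a8 and S100a9 fell far less, so the outcome of the bounds depends on that median.

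Treatment was swapped within pairs of the same time and replicate to ask whether chance can be excluded, with the real arrangement counted among the splits. Late, 1 of 32 splits, the real one, gave as many calls for H/L (408, highest other 237), M/L (589, 350), total (657, 449) and H/M (412, 229). No other split reached these counts. A share of 1 of 32 is the lowest that 32 splits can give, so this makes chance less likely but cannot exclude it. Early, the real split was again the 1 of 32 with as many calls for H/L (15, highest other 13) and total (27, 23). For the LPS difference in slopes (464, 431) it was 1 of 100. The margins of these counts were narrow, so chance is not excluded for them either. For M/L early chance cannot be excluded, since 2 of 32 splits gave at least the 12 calls and the highest other gave 14. Splits that swap a single pair keep the real treatment in the other pairs.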
